A study of Oryza sativa Indica Group with 6 samples.

How the data were processed

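The series holds 6 arrays with 2 dyes, or 12 channels, from the rice cultivars FR13A and IR24. Per the labels, seedlings were untreated or in 150 mM salt for 15 min or 24 h, with 2 arrays per condition that exchange the dyes. Groups, cultivars and dyes were taken from the labels alone. The arrays carry 21495 non-control probes, 1 per gene name, and 1080 control spots.

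Per the file headers, the scanner software was Agilent Feature Extraction 8.1.1.1. Spot intensities were deposited as mean pixel brightness per channel, with the median local background and with intensities that the software had background-corrected (method 7), spatially detrended (setting 1) and dye-normalized (method 6, LOWESS 0.25). The deposited log10 ratios are the software's processed Cy5 over processed Cy3 signal. The authors' series table holds the same log10 ratios with the sign of the 3 replicate 2 arrays turned, to within 0.005, so that its values read FR13A over IR24 by the labelled dyes. Other deposited columns are flags of the scanner software, per the file headers: well above background (2.6 SD of the background), saturated, and outlier.

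Mean intensities were read with limma 3.58.1 in R 4.3.3 with statmod 1.5.0. Background was corrected by normexp with an offset of 50, and log2 ratios were normalized within each array by loess with control spots at weight 0. Spots with an outlier flag were left out of the ratio fits, and 508 probes with such a spot were left out of the fits of single channels. A probe was tested when it was well above background in 1 cultivar on both arrays of at least 1 condition, which held for 20522 probes with the dyes as labelled and 20658 with 2 signs turned. The single-channel fits held 20019 and 20154 probes. Median brightness was 144 to 236 in Cy3 and 337 to 703 in Cy5, with 34 to 297 flagged and up to 142 saturated spots per channel and array.

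Differences between the cultivars, and their change in salt, were tested on the log2 ratio of each array by lmFit and eBayes, with 1 mean per condition and 3 residual degrees of freedom. Salt responses within a cultivar were tested on single channels after Aquantile normalization between arrays by lmscFit, with an intra-spot correlation of 0.532. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The 36 gene lists were matched by words in the array's descriptions and tested by camera with a preset correlation of 0.01 where at least 5 probes were tested, again with an estimated correlation, and by fry. A list of 3 circadian probes was too small and was not tested. These choices, the lists, the alternatives and the rule for naming genes were fixed before the data were examined.

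Among probes with an informative description (8909 of 21495), the rule named those with an adjusted p below 0.05 and 1 sign on every array compared. For the mean genotype difference and the 24 h responses it took the 10 largest changes each way, and for other comparisons the 5 largest each way. Where fewer than 5 passed, it took the 5 with the lowest p, which are said not to pass. For each list called it took up to 4 members past the threshold, or the 2 with the lowest p. No array name matched the gene table supplied, so names come only from the descriptions.

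Further comparisons were added after seeing the data, because 2 salt arrays ran against the other 4. They are the sign of these 2 arrays turned, the 2 arrays exchanged, the 4 other arrays alone, the 4 salt arrays pooled against the 2 untreated arrays, and 24 h against 15 min. The pooled ratio fits had 4 residual degrees of freedom, and the pooled single-channel fits had an intra-spot correlation of 0.741. The mean brightness of both channels, which does not depend on the dyes, was compared between salt and untreated arrays by lmFit and eBayes. The naming rule was kept for them, with 10 each way for the pooled genotype difference and salt responses.

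The alternatives fixed in advance were no background subtraction, the software's processed signals, median centring, no filter and a strict filter on dim probes, a term for the replicate number (also the dye), array weights, the authors' ratios, scan date as a random block, quantile normalization, the channels of 1 cultivar alone, 1 value per condition, a log2 change of at least 1 and each array left out in turn. Fits with an array left out kept the intra-spot correlation of the full fit, and a lone remaining array was assumed to vary like the other groups. The arrays were scanned on 3 days, with 4 arrays on 1 of them. The fits were tested on simulated data of 20019 probes with 100 probes changed: of 2-fold changes 90% were found for the untreated genotype difference, 81% for its change at 24 h, 56% for the 24 h response of FR13A and 80% for pooled responses. Of 4-fold changes 93% to 100% were found, with 8 to 18 false calls. These shares were not shown to hold for the fits with the dyes as labelled. There the salt arrays that ran against the others widen the spread shared by all conditions. The lowest adjusted p of the labelled untreated genotype difference was 0.103 (limma). A lack of calls in a labelled fit is therefore no evidence that 2-fold differences are absent.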

Results

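Transcript levels of 2 rice cultivars were compared on 6 oligonucleotide arrays with 2 dyes each. FR13A is an indica landrace known for its tolerance of submergence, and the submitters treat it as the salt-tolerant parent; IR24 is a modern indica cultivar that they treat as susceptible. Seedlings were left untreated or held in 150 mM salt for 15 min or 24 h, with 2 arrays for each of the 3 conditions. Untreated and 15 min plants were harvested 14 days after sowing and 24 h plants 15 days after sowing. Each array carried RNA of both cultivars from 1 condition, with FR13A in Cy5 on replicate 1 and in Cy3 on replicate 2. The sources used here name no tissue and do not say whether the replicates were separate plants, so the p-values measure only the spread between these arrays, which may be technical. Median spot brightness ran from 144 to 236 in Cy3 and from 337 to 703 in Cy5, and 87.3% to 95.1% of probes in Cy3 and 89.9% to 96.4% in Cy5 were well above background. Genes are named by the array's own descriptions, which often give a similar sequence of another species, together with the rice cDNA identifier.

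The FR13A over IR24 log ratios had no settled direction on 2 of the 6 arrays. Turned by the dyes in the labels, the untreated pair correlated at r = 0.71 across probes, whereas the 15 min pair correlated at r = -0.84 and the 24 h pair at r = -0.80. The arrays labelled 15 min replicate 2 and 24 h replicate 1 ran against the other 4, with r between -0.84 and -0.60 for every opposing pair. The authors' deposited ratios gave 0.73, -0.85 and -0.81 for the same 3 pairs. With the sign of these 2 arrays turned, every pair correlated at r between 0.57 and 0.84. Probes are not independent replicates, and turning was chosen after seeing the data. Results are therefore given with the dyes as labelled and again with the 2 signs turned, which the counts call aligned arrays. The direction of the turned values rests on the other 4 arrays, which include the untreated pair. These 4 are called arrays of settled direction because they run together under the labels. That they run together does not show that their labels are right. Turning was chosen so that the arrays run the same way, so counts from turned arrays are not independent evidence that they do. It also puts FR13A in Cy5 on both 15 min arrays and in Cy3 on both 24 h arrays. A dye effect then cancels over the pooled salt arrays but not within a salt time. The mean brightness of both dyes does not depend on which dye held which cultivar, and it was used for the salt response of both cultivars together.

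**Figure D1:**
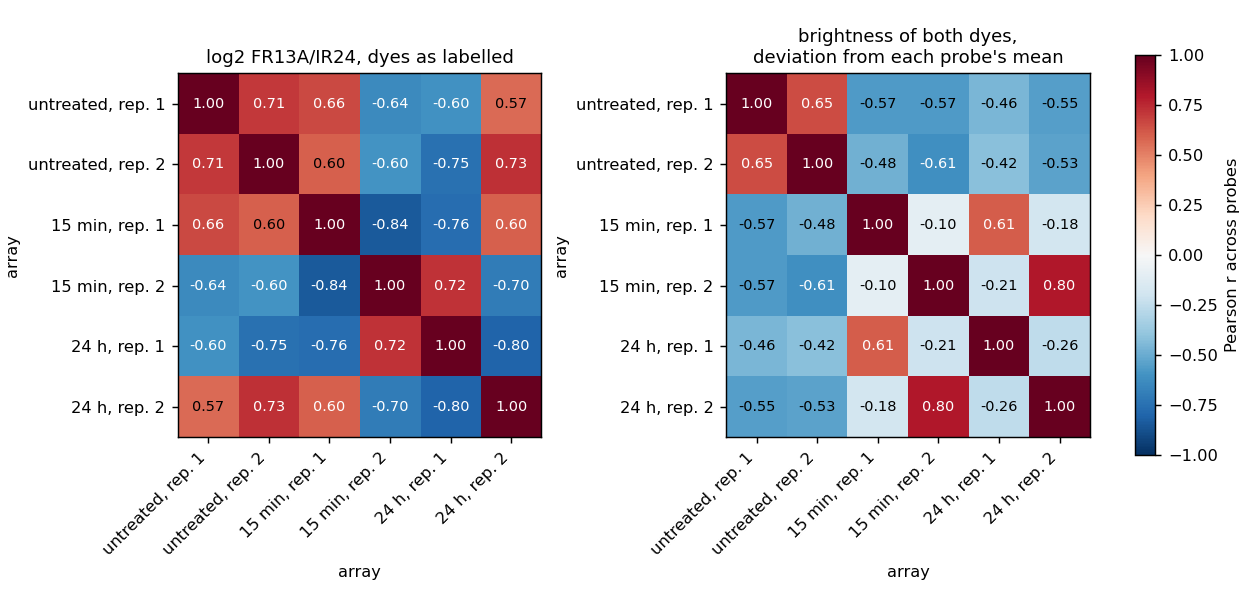
Pearson correlation across probes between the 6 arrays, for log2 FR13A/IR24 with the dyes as labelled (left) and for the deviation of each probe's brightness from its mean over the arrays (right); rows and columns are arrays. In the left panel 15 min replicate 2 and 24 h replicate 1 correlate negatively with the other 4 arrays, down to -0.84.

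Genotype differences in the absence of salt and over all conditions were the first comparison. With the dyes as labelled, a glutathione S-transferase described as OsGSTU17 (AK099489), of a detoxifying enzyme family, was higher in untreated FR13A by 1.96 ± 0.09 on the log2 scale (SE, n = 2 arrays), with adjusted p = 0.103. The class III chitinase OsChib3a (AK100973) measured 1.73 ± 0.11 (adjusted p = 0.281), a terpene synthase-like probe (AK110925) 3.17 ± 0.24 (adjusted p = 0.433), a Bowman-Birk trypsin inhibitor (AK070467) 1.34 ± 0.12 and the chlorophyll a/b-binding protein Cab26 (AK060800) 1.77 ± 0.16 (both adjusted p = 0.488). These 5 had the lowest p and none passed the test. In limma, 0 of 20521 probes passed for untreated plants (1541 at an unadjusted p below 0.05), 0 for the mean of the 3 conditions (365), 0 at 15 min (110) and 0 at 24 h (130). The opposed arrays of a salt condition cancel in its mean and widen the spread that all conditions share.

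With the 2 signs turned, FR13A exceeded IR24 most, among probes with an informative description, for AK105947, described as the dehydration-responsive protein RD22. The difference was 5.45 ± 0.22 on the log2 scale, or 43.7-fold (SE, n = 6 arrays, limma adjusted p = 1.92e-05). Also higher in FR13A were a small subunit of the carbon-fixing enzyme Rubisco (AK068266, 4.09 ± 0.10) and ACC oxidase, which makes ethylene (AK058296, 3.53 ± 0.11). The same direction held for an extracellular cystatin, a protease inhibitor (AK102139, 3.26 ± 0.07), a peroxidase (AK064918, 2.95 ± 0.06) and chalcone synthase, the entry enzyme of flavonoid synthesis (AK061132, 2.5 ± 0.13). IR24 exceeded FR13A for the rice 21kd polypeptide (AK105453), at -4.00 ± 0.05 or 16-fold (adjusted p = 8.24e-07), a peptidylprolyl isomerase of protein folding (AK064825, -2.93 ± 0.06) and a lectin-like protein (AK062520, -2.87 ± 0.10). It also exceeded FR13A for anthocyanidin reductase (AK059518, -2.87 ± 0.20), the MADS-box factor FDRMADS6 (AK061899, -2.74 ± 0.09) and a laccase (AK068047, -2.72 ± 0.26). Each of these 12 probes had 1 sign on all 6 turned arrays, which the naming rule required. Of the 5148 probes called in this comparison, 4362 had 1 sign. The other named probes higher in FR13A, by 2.63 to 3.99, were homologs of SGR2, RPB10, CHUP1 and a human embryonic protein. Those lower, at -2.72 to -2.63, were a retrotransposon gag (AK106705, with FR13A well above background on 2 of 6 arrays), an HC toxin reductase, a glycine-rich protein and an alcohol dehydrogenase-like probe.

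The count in limma of probes called: aligned arrays, FR13A over IR24, all 6 arrays, was 2630 higher and 2518 lower in FR13A among 20656. Of these 460 differed by at least 1 on the log2 scale. Median centring in place of loess left 1084, scan date as a random block 2567, 1 value per condition 2497 and the 4 arrays with no turned sign 1709. For probes called: aligned arrays, FR13A over IR24, untreated, 1582 were higher and 1359 lower. That total of 2941 became 1329 without untreated replicate 1, with median centring 303 and with array weights 1072. For probes called: aligned arrays, FR13A over IR24, 4 salt arrays, all scanned on 1 day, 1823 were higher and 1896 lower. Without 15 min replicate 1, 15 min replicate 2 or 24 h replicate 1 that total of 3719 became 2475, 2252 or 2474, and with median centring 628. The RD22-like probe measured 5.93 ± 0.38 untreated (n = 2) and 5.21 ± 0.27 in salt (n = 4), the Rubisco small subunit 4.05 ± 0.17 and 4.11 ± 0.12, and the 21kd polypeptide -4.32 ± 0.09 and -3.85 ± 0.06. Of the probes called higher, 918 were shared between the untreated and the salt arrays, where independent lists would share 139.6. Of those called lower 984 were shared, where independent lists would share 124.7. The 2 comparisons use different arrays and 1 estimate of the spread. Because 2 of the 4 salt arrays were turned to run with the untreated pair, a shared direction was partly built in. The excess over independent lists is therefore not independent evidence of a lasting difference. With the dyes as labelled limma called 0 probes over the 4 salt arrays (36 at an unadjusted p below 0.05). At 15 min alone 876 were higher and 1052 lower with the sign turned, and at 24 h 1005 and 1036. A dye effect does not cancel within a salt time after turning, so these per-time counts may hold one.

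**Figure D2:**
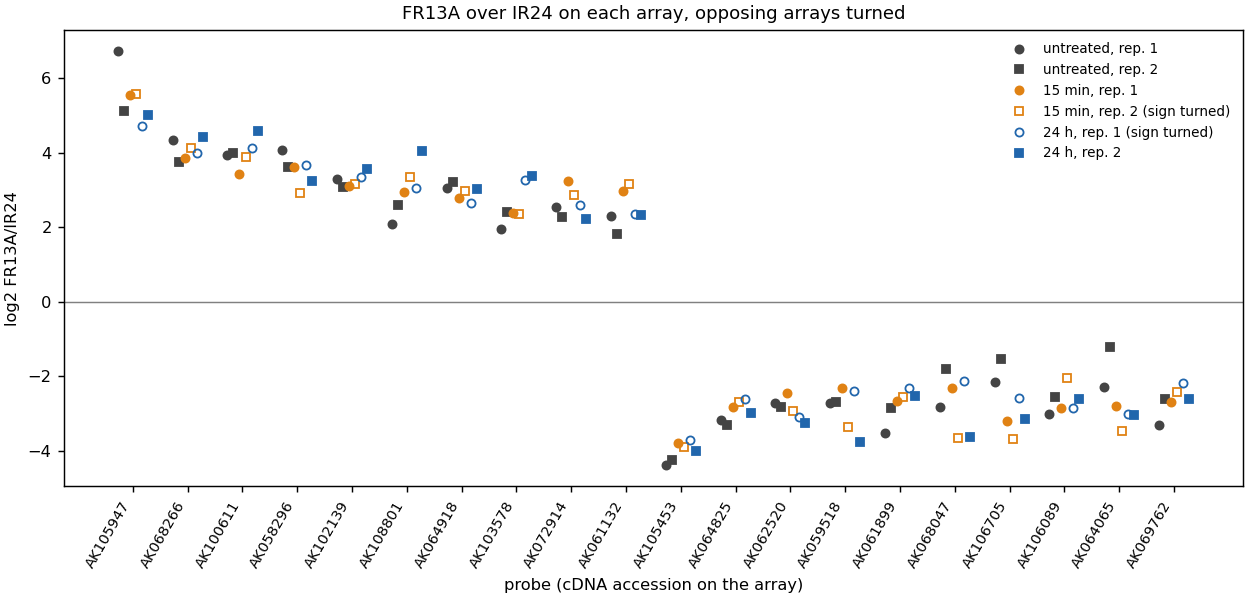
log2 FR13A/IR24 of the 20 named probes of the comparison over all arrays, 1 point per array (circles replicate 1, squares replicate 2, colour by condition, open symbols for the 2 arrays whose sign was turned). The RD22-like probe AK105947 averages 5.45 and the 21kd polypeptide AK105453 averages -4.00.

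With the signs turned, camera called no gene family between the cultivars. fry, a second test of lists, called 4, ion transport, pollen and anther, and fermentation (adjusted p = 0.0287 each) and jasmonate genes (adjusted p = 0.0355), each with members past the threshold both ways. Among sodium transport genes, the HKT1 transporter (AK105132), which moves sodium across membranes, was lower in FR13A, at -1.18 ± 0.06 (n = 6 arrays, adjusted p = 3.42e-05). A second HKT1-like probe (AK108663) was higher by 0.20 ± 0.03 (adjusted p = 0.00598), but IR24 was well above background on only 1 of the 6 arrays for it. Of the 23 probes of the preset salt and submergence list 1 was higher and 3 were lower in FR13A, and 4 passed adjusted over the list alone. In the wider ion transport list 12 probes were higher and 4 lower of 56, also when adjusted over the list alone. That list did not pass in camera (adjusted p = 0.399; adjusted p = 0.844 with an estimated correlation). Of 22 probes of protein phosphatase 2C, a family of which some members regulate abscisic acid signalling, 6 were higher and 6 lower. Of 150 resistance-type receptors 18 were higher and 19 lower. Of 47 fermentation and low-oxygen probes 9 were higher and 9 lower, and of 70 photosynthesis probes 5 and 9. With the dyes as labelled, camera called 2 lists, dehydrins and late embryogenesis proteins (median 0.25, adjusted p = 0.0458) and pathogenesis-related proteins (median 0.02, adjusted p = 0.00133). With an estimated correlation both had adjusted p = 0.89, and fry called no list with the dyes as labelled. No member of either passed over all probes, and adjusted over the list alone 0 dehydrin and 1 pathogenesis-related probe passed (limma). The LEA-like AK063984 measured 0.48 ± 0.25 and AK063645 0.25 ± 0.15, the latter -0.16 under median centring. The chitinase OsChib3a measured 0.70 ± 0.06 and a PBZ1 probe (AK099157) 0.88 ± 0.13. The dehydrins had adjusted p = 0.3, 0.0577, 0.617 or 0.272 without untreated replicate 1, untreated replicate 2, 15 min replicate 2 or 24 h replicate 1, 0.616 with median centring and 0.878 over the 4 arrays of settled direction. Their median was 0.15 without untreated replicate 1, 0.12 without 15 min replicate 2 or with median centring, and 0.01 over the 4 arrays. The pathogenesis-related list, whose median was -0.01 with median centring, 0.01 without untreated replicate 1 and 0.05 without untreated replicate 2 or 24 h replicate 2, had adjusted p = 0.102, 0.0632 or 0.0804 without untreated replicate 1, 15 min replicate 2 or 24 h replicate 1 and 0.282 over the 4 arrays. With the signs turned the dehydrins changed direction (median -0.11, adjusted p = 0.683), and the pathogenesis-related list had a median of 0.01 (adjusted p = 0.715).

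The salt response averaged over both cultivars was measured on the mean brightness of each array, over 4 salt and 2 untreated arrays. It was a comparison added after seeing the data. Such a mean can also move when 1 cultivar alone responds, so it does not show a shared response. Salt arrays were higher for a protein phosphatase 2C probe (AK063334) by 3.56 ± 0.83 on the log2 scale, or 11.8-fold (SE, n = 4 against 2 arrays, adjusted p = 0.0263), and for a homolog of LHY, a transcription factor of the circadian clock (AK111726), by 3.52 ± 0.25 or 11.4-fold (adjusted p = 0.00459). Also raised were nitrate reductase, the first enzyme of nitrate assimilation (AK102178, 3.07 ± 0.48), the water stress protein WSI76 (AK107065, 3 ± 0.40) and a syringolide-induced protein (AK111571, 2.99 ± 0.38). A phosphatase 2C homolog (AK069274, 2.96 ± 0.45) rose, as did the stress transcription factor OsNAC3 (AK067690, 2.87 ± 0.31), a DnaJ-like chaperone (AK071515, 2.76 ± 0.65), ferredoxin VI (AK069860, 2.71 ± 0.33) and a kinase homolog described as mapkkk1 (AK107168, 2.63 ± 0.60). Lower in salt were a cell wall invertase, which splits sucrose (AK072276, -2.73 ± 0.49), the metallothionein-like RicMT (AK062796, -2.62 ± 0.23), histone H4 (AK058741, -2.57 ± 0.34) and actin (AK063572, -2.53 ± 0.68). Salt arrays were also lower for an Erwinia-induced protein homolog (AK060664, -2.66 ± 0.25), the wax synthesis enzyme glossy8 (AK060501, -2.44 ± 0.31), a lipid transfer protein (AK071598, -2.43 ± 0.25), an ids4-like protein (AK107245, -2.31 ± 0.25) and ribosomal protein P2a (AK058815, -2.23 ± 0.12). Each of these 19 probes had 1 direction across arrays, which the naming rule required. In brightness the 4 salt arrays paired by replicate number. Their deviations correlated at 0.606 and 0.804 within replicates 1 and 2, and at -0.0991 and -0.256 within the labelled 15 min and 24 h pairs. For AK063334 brightness was 10.6 and 10.1 on the replicate 1 salt arrays and 12.9 and 12.8 on those of replicate 2. AK111726 ran from 11.2 to 12.1. A mean over 4 salt arrays can hide such a split.

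The count in limma of probes called: both genotypes averaged, salt over untreated, was 1924 higher and 2684 lower among 20154, with 970 changed by at least 1 on the log2 scale. The count depended on single arrays. Without untreated replicate 1 it was 96 (29 higher, 67 lower), without untreated replicate 2 it was 2770, and without 15 min replicate 2 it was 2834. It was 376 over the 4 arrays of settled direction. Untreated replicate 1 had 297 flagged spots, against 34 to 67 on the other arrays, and the lowest median Cy3 brightness, 144. Untreated replicate 2 had the lowest median Cy5 brightness, 337. All 4 salt arrays were scanned on 1 day and each untreated array on a day of its own, so no scan day held both. With scan date as a random block 2103 probes were higher and 2853 lower, but such a block cannot separate scan day from salt here.

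**Figure D3:**
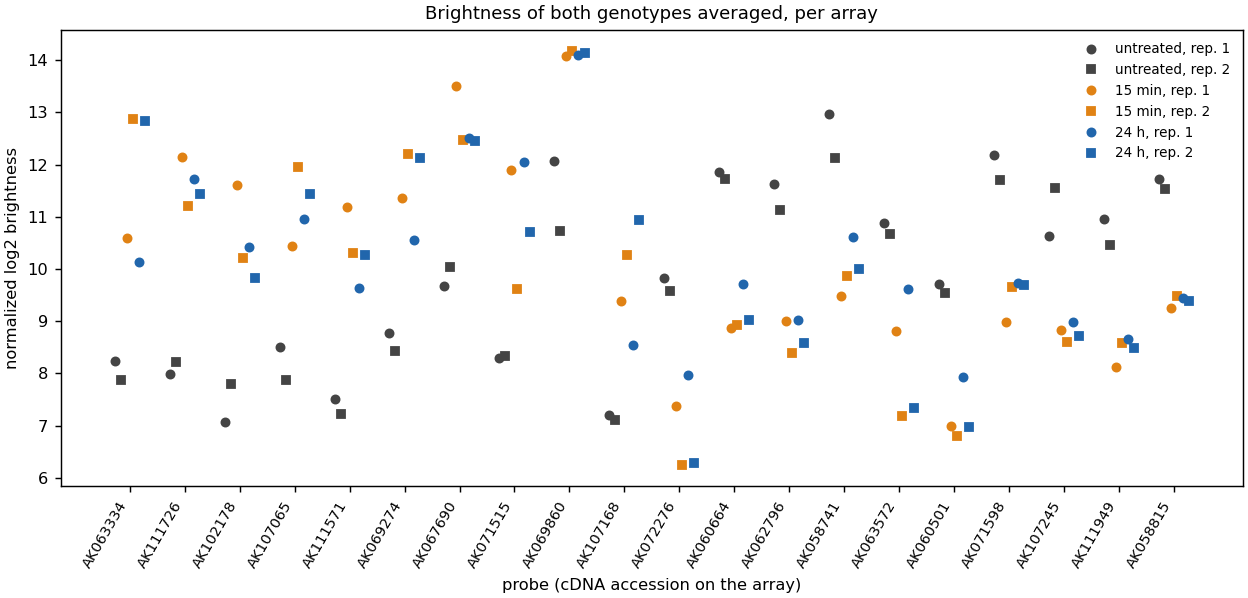
Normalized log2 brightness averaged over both dyes for the 20 named probes of the salt response, 1 point per array (circles replicate 1, squares replicate 2, colour by condition). The LHY-like probe AK111726 averages 8.1 on the 2 untreated arrays and 11.62 on the 4 salt arrays.

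Ribosomal protein genes formed the group that fell most clearly in salt. Of 161 probes 69 fell and 10 rose, and 82 fell and 12 rose adjusted over the list alone. The median change was -0.55 on the log2 scale (camera adjusted p = 2.95e-07; adjusted p = 0.844 with an estimated correlation). Ribosomal protein S10 (AK073846) fell by 1.91 ± 0.30 and an unspecified ribosomal protein (AK062150) changed by -1.76 ± 0.22, whereas a chloroplast rps3 and rpl22 homolog (AK060382) rose by 1.85 ± 0.22. fry also called the list (adjusted p = 0.0355), and the median was -0.41 without untreated replicate 1. Of 23 histone and cell cycle probes 9 fell and 2 rose (median -0.23, camera adjusted p = 0.061, fry adjusted p = 0.0491).

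Stress and signalling groups had individual members past the threshold, and camera called none of the groups below. fry called MAP kinases and WRKY factors (adjusted p = 0.0287 each). Of 28 MAP kinase probes 7 rose and 1 fell (median 0.26, adjusted p = 0.061), of 22 protein phosphatase 2C probes 5 rose and 1 fell (adjusted p = 0.399), and of 26 WRKY factors 6 rose and 0 fell (adjusted p = 0.48). Of 12 dehydrins and late embryogenesis proteins, which protect cells as they lose water, 2 rose and 10 did not pass (median 0.94, adjusted p = 0.148). No NAC probe matched by the list rose and 1 of 22 fell; OsNAC3 was not matched by the words of that list. Of 90 heat shock and chaperone probes 11 rose and 10 fell (adjusted p = 0.956), and of 134 ubiquitin and proteasome probes 9 rose and 25 fell (adjusted p = 0.399). Of 24 osmolyte synthesis probes 5 rose and 2 fell (adjusted p = 0.399), and of 55 ion transport probes 5 rose and 8 fell (adjusted p = 0.826). Markers that would show a change of tissue gave 5 rises and 7 falls of 69 photosynthesis probes (adjusted p = 0.595) and 3 and 4 of 34 root-preferred probes (adjusted p = 0.922). In limma 0 of 12 seed storage probes (adjusted p = 0.826) and 0 of 13 pollen and anther probes (adjusted p = 0.979) passed, also when adjusted over the list alone. In the preset list of 22 tested probes, 1 rose and 5 fell, and 7 passed adjusted over the list alone, with changes between -1.39 and 0.76.

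The response of each cultivar was next measured with the 2 signs turned and both salt times pooled. Turning decides which channel of 2 of the 4 salt arrays is read as which cultivar. In FR13A, salt arrays were higher than untreated arrays for the LHY homolog by 3.54 ± 0.24, or 11.6-fold (AK111726, SE, n = 4 against 2, adjusted p = 0.000201), for ferredoxin VI (AK069860, 3.15 ± 0.37) and for an invertase (AK061240, 2.75 ± 0.68). Lower were a lipoxygenase of jasmonate synthesis, rci-1 (AK066737, -3.23 ± 1.02, adjusted p = 0.0453), a delta-cadinene synthase-like probe (AK108761, -2.70 ± 0.70), the terpene synthase-like AK110925 (-2.64 ± 0.41) and the probenazole-inducible PBZ1 (AK071613, -2.51 ± 0.72). The Na+/H+ antiporter NHX1 (AK066168), which loads sodium into the vacuole, fell by 0.91 ± 0.17 (adjusted p = 0.00601). Ribosomal protein probes fell in 67 and rose in 8 of 161 cases (12 rises and 74 falls adjusted over the list alone; median -0.49, adjusted p = 1.56e-06; adjusted p = 0.844 with an estimated correlation). That median was -0.29 without untreated replicate 1 (adjusted p = 0.000389), and fry did not call the list (adjusted p = 0.0511). Histone and cell cycle probes fell in 10 and rose in 1 of 23 (2 rises and 10 falls adjusted over the list alone; adjusted p = 0.0242; adjusted p = 0.844 with an estimated correlation). Among them was PCNA, a replication factor (AK071591, -1.8 ± 0.25). Without untreated replicate 1 or 24 h replicate 2 that list had adjusted p = 0.0642 or 0.0601, and its median of -0.29 was -0.17 in the first. fry called it too (adjusted p = 0.0355), and ion transport genes (adjusted p = 0.0287), of which 5 rose and 8 fell. The count in limma of probes called: aligned arrays, FR13A, salt over untreated, was 1916 higher and 2355 lower. Median centring left 1842 and the 4 arrays of settled direction 42. Without untreated replicate 1, 15 min replicate 1 or 15 min replicate 2 the count was 1640, 2738 or 2623.

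In IR24, again with the signs of 2 salt arrays turned, salt arrays were higher for the protein phosphatase 2C probe AK063334 by 4.31 ± 0.83, or 19.8-fold (SE, n = 4 against 2, adjusted p = 0.0054), and a soluble acid invertase (AK072245, 4.15 ± 1.21, adjusted p = 0.0307). Also raised were the LHY homolog (AK111726, 3.49 ± 0.24), an ABA-responsive protein (AK063578, 3.30 ± 1.04) and OsNAC3 (AK067690, 3.20 ± 0.51). Lower were the cell wall invertase (AK072276, -3 ± 0.54), an ids4-like protein (AK107245, -2.71 ± 0.39), a histone H2A (AK074018, -2.48 ± 0.31) and ribosomal protein P2a (AK058815, -2.32 ± 0.15). Ribosomal protein probes fell in 81 and rose in 8 of 161 cases (10 rises and 86 falls adjusted over the list alone; median -0.63, adjusted p = 1.32e-08; adjusted p = 0.809 with an estimated correlation). fry called that list (adjusted p = 0.0287) and 6 that camera did not call, WRKY factors and resistance-type receptors (adjusted p = 0.0287 each), MAP kinases (0.03), phosphatases 2C and cytochromes P450 (0.0355 each) and pathogenesis-related proteins (0.0418). In the preset list 1 probe rose and 6 fell in each cultivar, and adjusted over the list alone 10 passed in FR13A and 7 in IR24. A salt-inducible protein homolog (AK065308) fell in IR24 by 1.70 ± 0.21 (adjusted p = 0.000893). The count in limma of probes called: aligned arrays, IR24, salt over untreated, was 2277 higher and 2633 lower. Median centring left 1820 and the 4 arrays of settled direction 519. Scan date as a random block gave 2739, but that fit used the IR24 channels alone. Without untreated replicate 1 or 15 min replicate 2 the count was 1111 or 3163.

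The 15 min and 24 h responses were also tested separately, with conditions and dyes as labelled and 2 arrays against 2. Since 1 array of each salt time is opposed, the cultivars nearly cancel there, and a labelled response of 1 cultivar also contains part of its untreated difference from the other, with the sign reversed. At 15 min, FR13A was higher for the LHY homolog (AK111726, 3.72 ± 0.36, adjusted p = 0.0135), ferredoxin VI (AK069860, 3.43 ± 0.61) and nitrate reductase (AK102178, 3.04 ± 0.53), and lower for the lipoxygenase rci-1 (AK066737, -3.96 ± 0.64) and histone H4 (AK058741, -2.84 ± 0.35). IR24 at 15 min was higher for nitrate reductase (AK102178, 3.89 ± 0.53, adjusted p = 0.0165) and Cab26 (AK060800, 3.56 ± 0.60), and lower for an Erwinia-induced protein homolog (AK060664, -3.32 ± 0.31) and the cell wall invertase (AK072276, -3.20 ± 0.67). At 24 h, FR13A was higher for the LHY homolog (AK111726, 3.60 ± 0.36, adjusted p = 0.0209), and WSI76 (AK107065, 2.98 ± 0.58). A ubiquitin-conjugating enzyme, OsUBC5b (AK066232, 1.82 ± 0.28), and a gibberellin 3beta-hydroxylase homolog (AK072410, 1.58 ± 0.19) were also higher, and it was lower for rci-1 (AK066737, -3.50 ± 0.64) and ribosomal protein P2a (AK058815, -2.14 ± 0.17). IR24 at 24 h was higher for the LHY homolog (AK111726, 3.33 ± 0.36, adjusted p = 0.0178), a beta-amylase homolog of starch breakdown (AK068968, 2.94 ± 0.64) and an early light-inducible protein (AK062972, 2.71 ± 0.46). It was lower for histone H2A (AK074018, -2.70 ± 0.47), the glycolytic enzyme enolase (AK073611, -2.02 ± 0.42) and replication protein A1 (AK060582, -1.93 ± 0.39). The 24 h plants were also 1 day older.

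limma called 235 probes higher and 577 lower in FR13A at 15 min, 192 and 426 at 24 h, 257 and 628 in IR24 at 15 min, and 266 and 541 at 24 h, among 20019. With the 2 signs turned the counts were 576 and 925, 545 and 818, 759 and 1249, and 798 and 1109. Each cultivar then had 1 dye at each salt time, so these turned counts may also hold a dye effect. Ribosomal proteins were called lower in all 4 responses, with median -0.58 (FR13A, 15 min), -0.51 (FR13A, 24 h), -0.58 (IR24, 15 min) and -0.58 (IR24, 24 h) and adjusted p = 5.48e-07, 4.3e-07, 2.2e-07 and 2.2e-07. With an estimated correlation each had adjusted p = 0.89. The median in FR13A at 24 h was -0.26 without untreated replicate 1 (adjusted p = 0.000101). Of 160 ribosomal probes 3 rose and 12 fell, 1 and 10, 2 and 24, and 1 and 21, in the same order. Adjusted over the list alone 8 rose and 39 fell, 5 and 37, 5 and 53, and 7 and 50. MAP kinases (median 0.36, adjusted p = 0.0375, with 1 of 28 risen) and resistance-type receptors (median 0.16, adjusted p = 0.0246, with 4 of 145 risen) were called higher in FR13A at 15 min, and adjusted over the list alone 1 probe of each passed. With an estimated correlation both had adjusted p = 0.89. Histone and cell cycle genes were called lower in FR13A at both times (adjusted p = 0.0458 each; adjusted p = 0.89 with an estimated correlation). Of 23 probes 3 fell each time, and adjusted over the list alone 1 rose and 7 fell at 15 min and 1 rose and 6 fell at 24 h. The MAP kinases had adjusted p = 0.112, the receptors 0.102 and the histones 0.112 at 15 min and 0.124 at 24 h without untreated replicate 1. Without 15 min replicate 1 the receptors had adjusted p = 0.0607 and the histones at 15 min 0.0508, and without 24 h replicate 2 the histones had 0.0593 and 0.309. The histone median of -0.31 at 15 min was -0.18 without untreated replicate 1 and -0.17 without 15 min replicate 1, and that of -0.25 at 24 h was -0.41 without 24 h replicate 1. With median centring the histones at 24 h had adjusted p = 0.0562, and fry called none of these lists.

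Every one of these 4 counts depended on single arrays. For probes called: salt response of FR13A, 15 min over untreated, the count was 0, 0, 0, 1, 221 and 210 without untreated replicate 1, untreated replicate 2, 15 min replicate 1, 15 min replicate 2, 24 h replicate 1 and 24 h replicate 2. In the same order it was 0, 0, 1, 1, 0 and 0 for FR13A at 24 h, and 0, 453, 9, 9, 0 and 0 for IR24 at 24 h. For probes called: salt response of IR24, 15 min over untreated, it was 0, 560, 0, 8, 340 and 336. Where limma called 0, between 2273 and 4325 probes had an unadjusted p below 0.05. With scan date as a random block, fitted on 1 cultivar's channels alone, the 4 counts were 138, 5, 32 and 0 (4304 unadjusted). The same fit without the block called 0 in each. These counts therefore differ from the main ones by the model as well as by the block. Within the day on which all salt arrays were scanned, limma called 0 probes between 24 h and 15 min in FR13A (111 at an unadjusted p below 0.05) and 0 in IR24 (224). With the signs turned these were 0 (325) and 0 (311), but each cultivar then changed dye between the 2 times. With the 2 arrays exchanged, an arrangement chosen after seeing the data, limma called 1441 and 1027 probes between the times. That arrangement puts arrays of like brightness together, so these counts are not independent evidence for it. Over the 4 arrays of settled direction limma called 281 probes in FR13A and 236 in IR24, but with 1 array per salt time the spread there came from the untreated pair alone, so these counts carry no replication of either time.

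Whether the cultivars responded differently to salt was tested as a change of the FR13A over IR24 ratio. With the signs turned and both times pooled, the ratio fell for a pathogenesis-related protein of class PR1 (AK107926), from 2.52 ± 0.73 untreated (SD, n = 2) to -1.11 ± 0.57 in salt (SD, n = 4), a change of -3.63 ± 0.42 (SE, adjusted p = 0.0476). It also fell for the terpene synthase-like AK110925 (-3.50 ± 0.19, adjusted p = 0.00633), the soluble acid invertase AK072245 (-2.34 ± 0.20, adjusted p = 0.0278), 1-deoxyxylulose 5-phosphate synthase of isoprenoid synthesis (AK100909, -2.22 ± 0.24) and a hexose transporter homolog (AK069202, -2.10 ± 0.22). It rose for histone H2A (AK074018, 2.10 ± 0.21, adjusted p = 0.0344), a cellulase-like probe (AK064349, 1.87 ± 0.17), OsD305 (AK100557, 0.98 ± 0.09) and a phosphatase homolog, Mdp1 (AK111457, 0.98 ± 0.08). limma called 9 probes with a rising and 32 with a falling ratio among 20656. The total of 41 was 8, 196, 4, 3, 5 and 81 without untreated replicate 1, untreated replicate 2, 15 min replicate 1, 15 min replicate 2, 24 h replicate 1 and 24 h replicate 2. In limma it was 0 under median centring (508 at an unadjusted p below 0.05), 0 over the 4 arrays of settled direction (1205) and 0 with the dyes as labelled (1276). It was 3 with scan date as a random block, 3 with array weights, 65 with the scanner software's signals and 68 with the deposited ratios. No scan day held both untreated and salt arrays, so that block cannot separate scan day from salt here either.

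By gene group, the FR13A over IR24 ratio shifted downward in salt for WRKY factors (median -0.29 over 26 probes, adjusted p = 0.000321) and pathogenesis-related proteins (median -0.11 over 92, adjusted p = 8.3e-05), and upward for ribosomal proteins (median 0.15 over 167, adjusted p = 4.71e-08). Each of these 3 had adjusted p = 0.809 with an estimated correlation. In limma 0 WRKY and 0 ribosomal probes passed, also when adjusted over the list alone; WRKY71 (AK108745) measured -0.72 ± 0.16 and WRKY69 (AK060018) -1.33 ± 0.34. Among pathogenesis-related probes 2 passed, PR1 and a beta-1,3-glucanase (AK067528, -0.76 ± 0.08, adjusted p = 0.033), and 1 rose and 12 fell adjusted over the list alone. Cell wall proteins (median -0.07, adjusted p = 0.00124; adjusted p = 0.914 with an estimated correlation) and cytochromes P450 (median -0.10, adjusted p = 0.0188; adjusted p = 0.809 with an estimated correlation) were also called lower. Over all probes 0 members of either passed in limma, and 1 and 7 fell adjusted over the list alone. The P450 median was 0.04 under median centring while the mean stayed negative at -0.11. Without untreated replicate 1 the WRKY, pathogenesis-related, cell wall and P450 lists had adjusted p = 0.116, 0.109, 0.632 and 0.28. Median centring gave adjusted p = 0.0521 for ribosomal proteins, 0.0904 for cell wall proteins and 0.119 for cytochromes P450, and without 24 h replicate 2 cell wall proteins had adjusted p = 0.0601. Without untreated replicate 1 the WRKY median was -0.15, the pathogenesis-related median -0.05, the cell wall median -0.02 and the P450 median -0.05. The ribosomal median was 0.05 (adjusted p = 0.0245) and the cell wall median -0.16 without untreated replicate 2, and the cell wall median was -0.03 without 24 h replicate 2. The pathogenesis-related median was -0.03 with median centring. fry called WRKY factors (adjusted p = 0.0287), pathogenesis-related proteins and cytochromes P450 (0.0355 each), but neither ribosomal (adjusted p = 0.119) nor cell wall proteins (adjusted p = 0.327). It also called jasmonate and fermentation genes (0.0287 each) and glutathione S-transferases (0.0394), which camera did not.

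With conditions and dyes as labelled, limma called 0 probes for the change of the ratio at 15 min (609 at an unadjusted p below 0.05) and 0 at 24 h (773); with the signs turned it called 0 (2851) and 0 (2297). It called 8 and 16 with the 2 arrays exchanged, and 31 and 11 over the 4 arrays of settled direction, where each salt time had 1 array. With the dyes as labelled the opposed salt arrays cancel, so the change of the ratio is mostly the untreated ratio with its sign reversed. Across probes the 2 correlated at r = -0.963 at 15 min and -0.948 at 24 h, against -0.475 and -0.45 with the signs turned; the untreated arrays enter both sides. The labelled values below therefore largely restate the untreated difference and are no evidence of a salt response by themselves. OsGSTU17 (AK099489) measured -2.20 ± 0.12 at 15 min (adjusted p = 0.306) and -1.46 ± 0.12 at 24 h, and the terpene synthase-like AK110925 -2.96 ± 0.34 and -3.44 ± 0.34 (SE, n = 2 against 2). camera called WRKY factors lower (median -0.23, adjusted p = 0.00583), ribosomal proteins higher (0.08, adjusted p = 0.00547) and cell wall proteins lower (-0.03, adjusted p = 0.0458) at 15 min. At 24 h it called aquaporins (-0.25, adjusted p = 0.0325), class III peroxidases (-0.09, adjusted p = 0.00368), pathogenesis-related proteins (-0.06, adjusted p = 0.00547) and cell wall proteins (-0.13, adjusted p = 4.3e-07) lower and ribosomal proteins higher (0.08, adjusted p = 0.0199). With an estimated correlation these lists had adjusted p = 0.89, and cell wall proteins at 15 min adjusted p = 0.893. In limma 0 members of each passed over all probes or adjusted over the list alone. With the signs turned, camera gave at 15 min WRKY factors -0.29 (adjusted p = 0.00175), ribosomal proteins 0.16 (adjusted p = 4.11e-08) and cell wall proteins -0.03 (adjusted p = 0.109). At 24 h it gave aquaporins 0.09 (adjusted p = 0.926), peroxidases -0.10 (adjusted p = 0.0757), pathogenesis-related proteins -0.11 (adjusted p = 0.00105), cell wall proteins -0.12 (adjusted p = 0.000124) and ribosomal proteins 0.10 (adjusted p = 3.18e-05). With an estimated correlation none of these turned lists passed (lowest adjusted p = 0.842), and fry called none of them (lowest adjusted p = 0.0953). A dye effect does not cancel within a salt time after turning. These turned values may therefore hold one, with opposite signs at 15 min and 24 h.

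Each of these 8 list calls was lost when single arrays were left out. At 15 min, WRKY factors had adjusted p = 0.194 and 0.261 without untreated replicate 1 and 15 min replicate 1. Ribosomal proteins had adjusted p = 0.17 and 0.895 without untreated replicate 2 and 15 min replicate 1, with a median of -0.03 in the latter. Cell wall proteins had adjusted p = 0.876, 0.162, 0.0795, 0.0855 and 0.101 without untreated replicate 1, 15 min replicate 1, 15 min replicate 2, 24 h replicate 1 and 24 h replicate 2, and their median was 0.02 in the first. At 24 h, aquaporins had adjusted p = 0.112, 0.0665, 0.215, 0.165 and 0.0531 without untreated replicate 1, untreated replicate 2, 15 min replicate 1, 24 h replicate 1 and 24 h replicate 2. Peroxidases had adjusted p = 0.382 and pathogenesis-related proteins 0.134 without untreated replicate 1. Without 24 h replicate 2 peroxidases, pathogenesis-related, ribosomal and cell wall proteins had adjusted p = 0.237, 0.103, 0.407 and 0.07, and without untreated replicate 2 ribosomal proteins had 0.29. With median centring ribosomal proteins had adjusted p = 0.678 at 15 min and 0.672 at 24 h, and cell wall proteins at 15 min had 0.595, with a median of 0.03. Over the 4 arrays of settled direction cell wall proteins at 15 min had adjusted p = 0.147 and aquaporins 0.343, and with the scanner software's signals aquaporins had 0.0667. fry called none of the 8.

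The medians of these labelled lists moved as well. At 15 min the WRKY median of -0.23 was -0.14 without untreated replicate 1 or 15 min replicate 1. The ribosomal median of 0.08 was 0.13, 0.04 and 0.20 without untreated replicate 1, untreated replicate 2 and 15 min replicate 2, and the cell wall median of -0.03 was -0.10 and -0.06 without untreated replicate 2 and 15 min replicate 1. At 24 h the aquaporin median of -0.25 was -0.38 and -0.05 without untreated replicate 2 and 24 h replicate 1, and the peroxidase median of -0.09 was -0.20 and -0.03 without untreated replicate 2 and 24 h replicate 2. The pathogenesis-related median of -0.06 was -0.02, -0.13, -0.12 and -0.03 without untreated replicate 1, untreated replicate 2, 24 h replicate 1 and 24 h replicate 2. The ribosomal median of 0.08 was 0.02, 0.15 and 0.04 without untreated replicate 2, 24 h replicate 1 and 24 h replicate 2. The cell wall median of -0.13 was -0.03, -0.23 and -0.07 without untreated replicate 1, untreated replicate 2 and 24 h replicate 2.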

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

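In this part, the tests of the 2 opposed arrays and of scan date, sequence mismatch and sign flips were chosen only after the result was seen; the brightness-matched lists and the test of resistance-type receptors were written before their values were computed. A difference between the cultivars in their response to salt marked 41 probes, tested as a change of the FR13A over IR24 ratio with 2 signs turned. The ratio rose for histone H2A (AK074018, 2.10), a cellulase-like probe (AK064349, 1.87), OsD305 (AK100557, 0.98) and Mdp1 (AK111457, 0.98). It fell for PR1 (AK107926, -3.63), a terpene synthase-like probe (AK110925, -3.50), a soluble acid invertase (AK072245, -2.34), deoxyxylulose phosphate synthase (AK100909, -2.22) and a hexose transporter (AK069202, -2.10). These 9 probes stood at -3.63 to 2.10 when all 6 arrays were used, and 0 probes passed in limma over the 4 arrays of settled direction (1205 at an unadjusted p below 0.05).

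The first pattern is that 15 min replicate 2 and 24 h replicate 1 ran against the other 4 arrays. An exchange of these 2 arrays, with their dyes, could produce it: the brightness profiles paired them across the labelled conditions, the lower exchanged pair exceeding the higher labelled pair by 0.705 in correlation (95% bootstrap interval over probes 0.66 to 0.749). Wrong dye entries alone could also produce opposed ratios, and the labelled pairs' higher brightness correlation of -0.0991 cannot exclude that, since a batch shared by arrays of 1 replicate number would pair them in the same way. With every label right, a genotype difference that reverses in salt would make the 2 arrays of a salt condition run together. Their higher correlation of -0.80 excludes that reading. It cannot exclude a reversal with the other array of each salt time wrongly labelled, since that pair would be opposed in the same way. In that case 2 of the 4 arrays called settled, 15 min replicate 1 and 24 h replicate 2, would have the wrong direction. No biology was drawn from the exchanged arrangement with the salt times apart. With the times pooled an exchange gives the same groups and dyes as turning, so the pooled turned results are also those of an exchange.

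The second pattern is the lower brightness of ribosomal protein probes in salt. Bright probes might read lower on the salt arrays, but in both cultivars the ribosomal median lay at percentile 0 of 10000 random lists matched on brightness, which excludes this. The medians, with the signs turned for the single cultivars, were -0.49 in FR13A (matched lists -0.09 to 0.08), -0.63 in IR24 (-0.06 to 0.12) and -0.55 in both together (-0.07 to 0.10). Scan date could also produce the pattern and cannot be told apart from salt, since 0 scan days held both untreated and salt arrays.

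The third pattern is the spread of genotype differences over gene families, with the signs turned. Resistance-type receptors, which vary between rice cultivars, might differ more often than other probes, but 24.7% of 150 such probes and 24.9% of the others passed (Fisher's exact test, p = 1), with 20.6% at matched brightness. The bound set beforehand counted any p of 0.05 or more against this, but such a p does not show equal shares, so it stays open. Sequence mismatch under a probe could lower a cultivar's signal without a change of transcript level, and the share of 24.7% cannot tell the 2 apart without probe and genome sequences.

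Flips of the arrays' signs were counted for 3 results. With the dyes as labelled, all 32 of 32 flips gave at least the 0 calls of the labelled signs, and the highest gave 5131, the flip that turned the 2 opposed arrays, whose structure is the first pattern above. Any flip reaches a count of 0, so this decides nothing about chance. With the 2 signs turned, 1 of 32 flips reached 5148 calls, the turned signs themselves, and the next gave 755; the signs were chosen from the data, so this cannot tell. Over the 4 salt arrays 1 of 8 flips reached 3719 calls and the next gave 0, and 8 flips are too few to tell.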

How the results depend on the processing

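Per channel 87.3% to 96.4% of probes were well above background, and probes well above it in neither cultivar on both arrays of any condition were not tested. Among named probes 3753 values under alternatives kept direction and side of the threshold, 1027 kept direction but no longer passed, 55 newly passed and 6 changed sign; 257 counts stayed within 1.5 times of the first and 139 did not. The cause was not tested for any of them. Scan-date blocks were fitted for probes only, so lists have no p there. For the salt response of 1 cultivar the block was fitted on that cultivar's channels alone. Those counts differ from the main ones by the model as well as by the block.

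With the 2 signs turned, with the 2 arrays exchanged and over the 4 arrays of settled direction (all chosen after seeing the data), counts were 5160, 4798 and 2272 for probes called: FR13A over IR24, mean of the 3 conditions, 2905, 2621 and 1648 for probes called: FR13A over IR24, untreated, 1928, 1651 and 508 for probes called: FR13A over IR24, 15 min of salt, and 2041, 2177 and 691 for probes called: FR13A over IR24, 24 h of salt, against 0 as labelled. The change of the ratio gave 8 (exchanged) and 31 (4 arrays) at 15 min and 16 and 11 at 24 h, and 24 h over 15 min gave 1441 and 281 in FR13A and 1027 and 236 in IR24, against 0 (limma); with 4 arrays and the times apart, the spread came from the untreated pair alone.

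For probes called: salt response of FR13A, 15 min over untreated, main count 812, the count was 8 with median centring, 305 with the replicate block, 0 for 1 cultivar's channels alone (4442 at an unadjusted p below 0.05), 138 with scan date as a random block, 1501 turned, 5923 exchanged, 521 over 4 arrays and 446 with a log2 change of at least 1. In the same order, probes called: salt response of FR13A, 24 h over untreated, 618, gave 3, 153, 0 (4135), 5, 1363, 4749, 1122 and 369. Without the 4-array value, probes called: salt response of IR24, 15 min over untreated, 885, gave 8, 573, 0 (4378), 32, 2008, 6034 and 549, and probes called: salt response of IR24, 24 h over untreated, 807, gave 0 (2380), 101, 0 (4161), 0 (4304), 1907, 5500 and 473, and 459 with the software's processed signals.

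With the 2 signs turned, probes called: aligned arrays, FR13A over IR24, all 6 arrays, gave 1084 with median centring, 2567 with scan date, 0 with the dyes as labelled (521), 1709 over 4 arrays, 460 with a log2 change of at least 1 and 2497 with 1 value per condition. In untreated plants probes called: aligned arrays, FR13A over IR24, untreated, gave 303, 0 as labelled (2206), 1060 and 590, and 1072 with array weights. In salt, probes called: aligned arrays, FR13A over IR24, 4 salt arrays, gave 628, 1278 with scan date, 0 as labelled (36), 718 and 470. The change of the ratio, 41, gave 65 with processed signals, 0 with median centring (508), 4 with the turned dye as a term and 3 with array weights. It gave 68 with the authors' ratios, 3 with scan date, 0 as labelled (1276), 0 over 4 arrays (1205) and 25 with a log2 change of at least 1.

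Among salt responses, probes called: aligned arrays, FR13A, salt over untreated, gave 1842 with median centring, 42 over 4 arrays and 876 with a log2 change of at least 1, and probes called: aligned arrays, IR24, salt over untreated, gave 1820, 519 and 1195, and 2739 with scan date. For probes called: both genotypes averaged, salt over untreated, the count was 7751 with the arrays exchanged and the times fitted separately, 376 over 4 arrays and 970 with a log2 change of at least 1. With the dyes as labelled these 3 gave 3677, 3897 and 4597. Lists called were 46 over 4 arrays, 0 with an estimated correlation and 0 with fry as labelled, and 16 exchanged with the times apart, 16 over 4 arrays, 0 with an estimated correlation and 24 with fry when turned. With the times pooled an exchange gives the same groups and dyes as turning, so it could not move these 2 counts by itself.

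With each array left out, the labelled genotype differences, their changes and 24 h over 15 min stayed at 0 (limma; 68 to 1749 at an unadjusted p below 0.05). The salt responses ran from 0 to 221 and 0 to 1 in FR13A and from 0 to 560 and 0 to 453 in IR24, at 15 min and 24 h, and the lists from 7 to 30. With the 2 signs turned the genotype difference ran from 3742 to 5189 over all arrays, 1329 to 3007 untreated and 2252 to 4059 in salt, and its change from 3 to 196. The pooled salt response ran from 1640 to 3845 in FR13A, 1111 to 4967 in IR24 and 96 to 3821 in both, and the lists from 4 to 17.

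Replicate numbers were not taken to pair the arrays, since the ratio deviations of same-numbered arrays did not all correlate above 0.1: 0.18, 0.0892 and -0.761 as labelled, and 0.0704, 0.0623 and 0.384 with the signs turned. Brightness deviations of the same-numbered salt arrays did correlate, at 0.606 and 0.804. The replicate block, which is also a dye term, moved no other count beyond 1.5 times but ended the labelled call of dehydrins (camera adjusted p = 0.0566). In the turned ratio fits this term followed the turned dyes and not the replicate number. Among the salt arrays it then separated 15 min from 24 h. Sign changes were 0.04 for AK070467 at 15 min, -0.10 for AK060800 and -0.07 for AK099489 at 24 h with the signs turned, 0 for AK100611 and 0.17 for AK064065 over the salt arrays with the dyes as labelled, and -0.16 for AK063645 over all conditions with median centring.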

Other observations

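In this part no test of an explanation was chosen, before or after its result was seen. Further gene groups had members past the threshold in salt on the mean brightness of both cultivars. Of 147 resistance-type receptor probes 22 rose and 6 fell, and 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.106). Of 55 MYB factors 4 rose and 10 fell, of 78 calcium signalling probes 5 rose and 12 fell, of 84 class III peroxidases 6 rose and 12 fell, and of 57 antioxidant enzyme probes 1 rose and 7 fell. Of 39 AP2/ERF and DREB factors 4 rose and 6 fell, of 50 glutathione S-transferases 7 rose and 5 fell, of 22 lipid transfer proteins 0 rose and 4 fell, and of 105 cytochromes P450 12 rose and 11 fell. camera called none of these lists, and fry called 1, resistance-type receptors (adjusted p = 0.0346).

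The preset genes not named above were read with the signs turned. A membrane-associated salt-inducible protein homolog (AK101805) rose in FR13A in salt by 0.80 ± 0.16 (adjusted p = 0.00675), and a second such homolog (AK063911) fell in FR13A by 1.15 ± 0.20 (adjusted p = 0.00445). In IR24 the salt-inducible protein homologs AK067226 and AK067137 were lower in salt, at -0.40 ± 0.09 and -0.68 ± 0.18. The salT probe AK105091, a mannose-binding protein known from salt-treated rice, was lower in FR13A, at -0.14 ± 0.04 (adjusted p = 0.0335).

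Between the cultivars, the 2 lists with the lowest p for their share of called probes were cell wall proteins, at 13% of 123 (Fisher's exact test, adjusted p = 0.0556), and protein phosphatases 2C, at 54.5% of 22 (Fisher's exact test, adjusted p = 0.0805). Neither passed. The hour of harvest is not given in the labels, so the rise of the LHY homolog (AK111726), a clock gene, by 3.52 in salt is given as a value only. Column medians of the authors' ratios were 0 apart from 1 array at -0.000171.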
